A study of Mus musculus with 36 samples.

How the data were processed

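The data are values for 36 single-channel Affymetrix arrays of the mouse left ventricle, 3 per group of surgery (SHAM or TAC) and time of day. Per the labels' protocols, hearts were frozen in liquid nitrogen, RNA was extracted with Trizol, and biotin-labelled cRNA was prepared from 6 ug of total RNA. The deposited table holds log-scale values for 22690 probe sets, taken here as log2. The base, the summarisation of probes and the normalization are not given in the sources used here. Every probe set had a median within 1e-06 of 0 over the 18 SHAM arrays and over the 18 TAC arrays, so the values were centred within each surgery before deposit. Array medians ranged from -0.036 to 0.027. No pair of arrays held identical values. Group and time were taken from the sample titles. The labels used here do not give the light schedule, strain or sex.

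Probe sets were named through the platform annotation, updated through Entrez identifiers, of which 20351 of 20380 matched and 0 changed a symbol. Of the 22690 probe sets, 20393 had 1 gene symbol (13 of them controls, left out), 691 had several and 1606 were not listed. The values of all probe sets of a gene were averaged, giving 12393 genes, of which 4956 had several probe sets.

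Several choices fixed before the data were examined could not be kept, because they need levels that the centring removed. The comparison of levels between TAC and SHAM, at each time, over the day and for gene lists, was not made. The filter on the 25% dimmest genes and the rule of the brightest probe set were replaced by no filter and the mean over probe sets. The empirical Bayes step was run without an intensity trend, since the mean level that the trend uses was centred away, and the planned version with a trend was run as an alternative. The part of the rule for named genes that used the level contrast was void. Of each list, the up to 4 members with the smallest joint p of a rhythm in either surgery were eligible to be named instead, a replacement made after preliminary results had been seen. The rest of the rule stood: the 10 largest amplitudes among genes passing in each surgery, the 10 smallest p for the difference of rhythm and of time course, and every measured clock gene, with clone-like symbols skipped. Of the ranked differences, the text names those that passed. Genes named outside the rule are said to be so.

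Rhythms were tested with limma 3.58.1 in R 4.3.3. The linear model held a mean, a cosine and a sine of 24 h for each surgery over all 36 arrays, with 1 estimate of the spread per gene. Moderated F-tests asked whether the 2 rhythm terms of a surgery were 0 and whether those of TAC and SHAM were equal. A model of 12 group means gave the F-test of the interaction of surgery and time on 5 degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes, and the threshold was 0.05. Standard errors of amplitudes and peak times came from the delta method with the moderated variance, with 18 arrays per surgery. That variance was shared by both surgeries, so an SE given for TAC does not measure the spread of the TAC mice alone. The means of 57 lists (35 gene lists and 22 cell type marker lists, fixed before the data were examined) were fitted in the same way, and this test, added after the data had been seen, stands in for the planned test of list shifts. The clock comparison took the 17 members with a rhythm common to both surgeries and relabelled surgery within each time 100000 times after centring each gene within surgery. The shift in peak time was tested in the same way and was added later, as was the comparison of the SD around the group means, with 10000 relabellings of surgery within time. No group held enough arrays for an outlier test.

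The tests were checked on simulated data with the measured spread of the 12393 genes. Of 200 genes given an amplitude of 0.2 in SHAM, 92.5% were recovered, and of 200 given a difference of 0.2 in rhythm, 71.5%. The time course test recovered 51% of the latter. At an amplitude of 0.5 the figures were 98.5% and 97%. Of 348 calls of a difference in rhythm, 11 were false. The simulation assumed the same spread in both surgeries and independent arrays.

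Alternatives were quantile normalization, centring of each array on its median, array weights, the empirical Bayes trend with and without robust fitting, the replicate number as a block, a test for any shape, the arrays of 1 surgery alone, a fold minimum of 1.5, and leaving out each array and each replicate number. Added after the data had been seen were the probe set with the largest SD, each probe set tested by itself, leaving out genes with an SD below the median, leaving out 4 arrays with a mean above 1 for thymocyte or airway markers, atrial and white adipocyte marker means as covariates, and the mean of the matrix list as a covariate of each surgery. Figures were drawn with matplotlib 3.10.9.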

Results

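Messenger RNA of the mouse left ventricle was measured on 36 Affymetrix expression arrays, 1 per mouse. The mice had undergone either transverse aortic constriction (TAC), an operation that narrows the aortic arch and loads the left ventricle with pressure, or a SHAM operation. They were killed 8 weeks later at 6 times of day, named ZT03, ZT07, ZT11, ZT15, ZT19 and ZT23 in the sample titles, 4 h apart. Each of the 12 groups of surgery and time held 3 mice, described in the labels as biological replicates, so 18 arrays came from each surgery. The design addresses how gene expression over the day in the loaded heart compares with that in the SHAM heart. The number of arrays limits the precision of every value given.

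The deposited values were relative, with a median of 0 over the 18 SHAM arrays and, separately, a median of 0 over the 18 TAC arrays for each of the 22690 probe sets. A difference in level between TAC and SHAM, averaged over the day or at any time, could therefore not be estimated from these values, and no gene is reported as higher or lower after TAC. What could be compared was the course over the day within each surgery, the difference between the courses, and the spread between mice. Values were taken as log2, which the sources used here do not state. Amplitudes are from the mean to the peak of a fitted 24-h curve on this scale, and folds from peak to trough rest on it.

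In SHAM hearts, Dbp and Nr1d1 had the largest amplitudes among genes that passed the test. Dbp, a transcription factor driven directly by the clock, had an amplitude of 1.59 ± 0.12 (SE, n = 18) and peaked at ZT10.3. Nr1d1, which encodes the clock repressor REV-ERB alpha, had an amplitude of 0.97 ± 0.07 with a peak at ZT6.65. G0s2, an inhibitor of triglyceride lipase, peaked at ZT17.7 with a peak-to-trough fold of 3.21. Zbtb16, a transcription factor gene induced by glucocorticoids, peaked at ZT12.3 with a fold of 2.91. The next largest amplitudes were those of Tcap, a titin-binding Z-disc protein (0.75 ± 0.07), the protease inhibitor gene Timp4 (0.75 ± 0.11), the clock repressor gene Nr1d2 (0.75 ± 0.06), the transcription factor gene Cebpb (0.69 ± 0.08), Pdk4, an inhibitor of pyruvate dehydrogenase (0.64 ± 0.17, a call held in 23 of 50 alternatives), and the prolyl hydroxylase gene Egln3 (0.64 ± 0.06). Of 12393 genes tested, 692 had a 24-h rhythm in SHAM at an adjusted p under 0.05 in the limma cosinor fit, and 117 of them had a peak-to-trough fold of at least 1.5. Arrays weighted by their quality gave 3126 genes, quantile normalization 1393, the 18 SHAM arrays alone 1166, and a test for any shape 418. Without all arrays of replicate number 2, 119 genes passed.

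**Figure D1:**
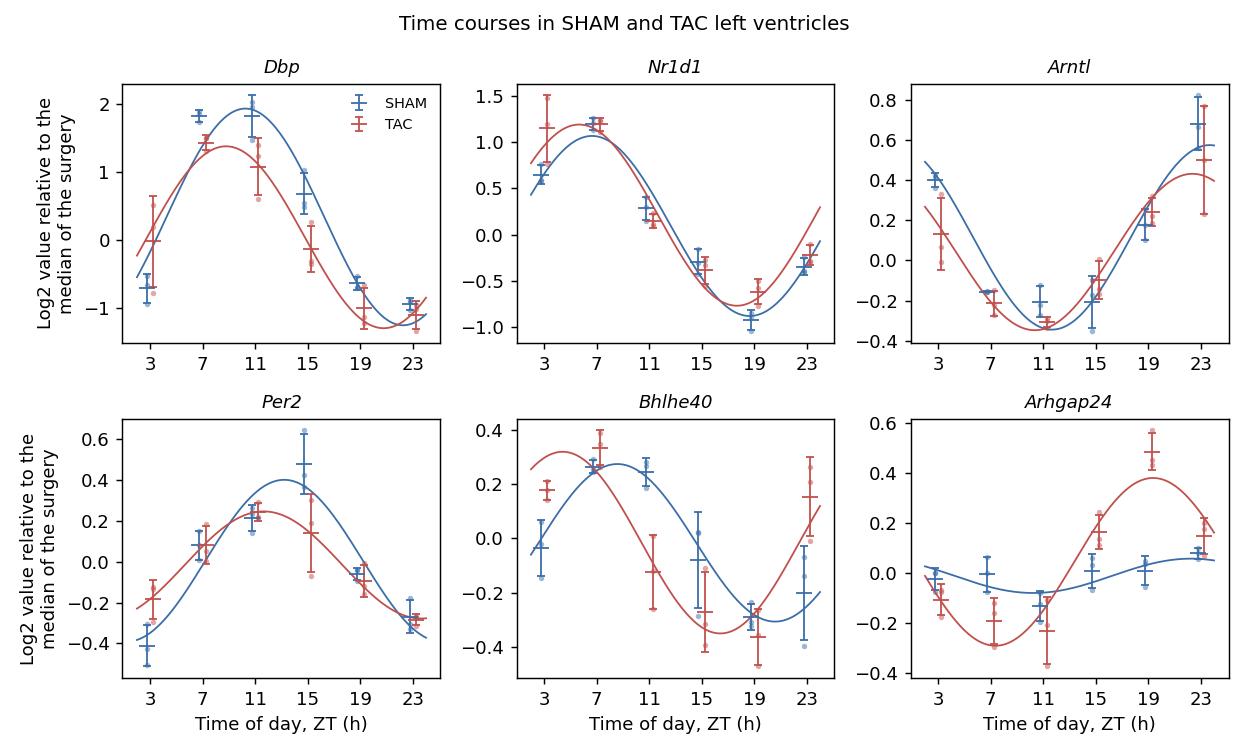
Log2 values relative to the median of each surgery against time of day for 6 genes, with points for single mice, bars for the mean ± SD of 3 mice and lines for the fitted 24-h curves. Dbp had an amplitude of 1.59 in SHAM and 1.34 in TAC, and Bhlhe40 peaked at ZT8.58 in SHAM and ZT4.41 in TAC.

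In TAC hearts, Dbp (amplitude 1.34 ± 0.12 (SE, n = 18), peak ZT8.78) and Nr1d1 (0.98 ± 0.07, peak ZT5.67) again had the largest amplitudes. They were followed by Thrsp, a gene of lipid synthesis and 1 of the white adipocyte markers (0.70 ± 0.17, or 0.29 and not passing with atrial and adipocyte marker means as covariates), the clock repressor gene Nfil3 (0.65 ± 0.08), Rcan1, a regulator of calcineurin (0.63 ± 0.13), Nr1d2 (0.61 ± 0.06) and Gdap10 (0.56 ± 0.12). Rrad, a small GTPase gene, peaked at ZT0.28 with an amplitude of 0.56 ± 0.11. Xirp1, which encodes an actin-binding protein of the intercalated disc, peaked at ZT19.5 with an amplitude of 0.56 ± 0.07, and the amino acid transporter gene Slc38a2 peaked at ZT19.9 with 0.54 ± 0.07. A rhythm passed the limma test for 539 genes in TAC, and 77 of these had a fold of at least 1.5. Of the 539, 241 (44.7%) peaked between ZT16 and ZT20, against 162 of 692 (23.4%) in SHAM. This difference between the shares was not tested. This count used 1 estimate of the spread over both surgeries, while the more variable 18 TAC arrays alone gave 142 genes and array weights 2298. The order of the surgeries turned in a test for any shape (652 in TAC against 418 in SHAM), with the mean of the matrix genes as a covariate (738 against 540) and without SHAM ZT03 replicate 3 (617 against 601). At an unadjusted p under 0.05 in the limma test it turned too, with 2450 genes in TAC against 2331 in SHAM. Without all arrays of replicate number 2, 116 genes passed, and of 99 random rearrangements of the time labels of the TAC arrays, the highest counts were 513, 316 and 241.

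**Figure D2:**
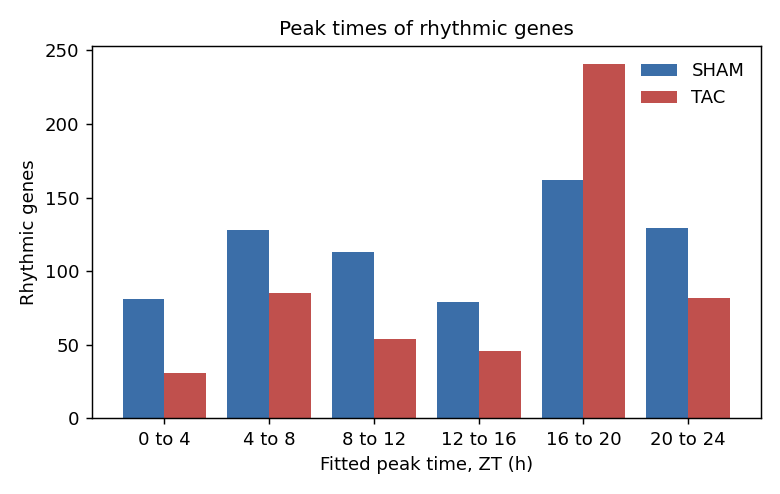
Number of rhythmic genes by fitted peak time in bins of 4 h, for SHAM and for TAC. The tallest bar is that of TAC between ZT16 and ZT20, with 241 genes.

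Rhythms passed in both surgeries for 248 genes, where 30.1 would be shared by independent lists of these sizes. The lists were not independent, since both tests used the same estimate of the spread of a gene, which can raise the overlap. Of the 248 genes, 190 had peak times less than 2 h apart, and the median TAC minus SHAM difference in peak time was -0.71 h. Of the clock list, 18 of 20 members were measured and 16 were rhythmic in each surgery, as was the count adjusted over the list alone. The activators Arntl and Clock peaked at ZT23.7 and ZT23.6 in SHAM and at ZT22.4 and ZT22.7 in TAC. Per2 peaked at ZT13.2 in SHAM and ZT11.6 in TAC, and Cry1 at ZT19.0 and ZT18.2. Rora and Bhlhe41 did not pass in either surgery.

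Heat shock genes followed a rhythm together in both surgeries, with the mean of 17 measured members peaking at ZT19.8 in SHAM (amplitude 0.22 ± 0.04, adjusted p = 0.00116) and at ZT17.7 in TAC (0.18 ± 0.04, adjusted p = 0.00645). In SHAM 9 members passed (12 adjusted over the list alone) and in TAC 6 (8 adjusted over the list alone). The tests of this and the other list means used 1 estimate of the spread over both surgeries. All 17 heat shock members varied more between mice in TAC (median log2 ratio of SDs 0.79), so the TAC test of this list was lenient. The chaperone gene Hsp90aa1 had an amplitude of 0.42 ± 0.06 in SHAM and 0.36 ± 0.06 in TAC, and the co-chaperone gene Dnaja1 0.47 ± 0.07 and 0.37 ± 0.07. The mean of the 24 glycolysis genes peaked at ZT18.0 in SHAM (0.05 ± 0.01, adjusted p = 0.0472) and ZT19.6 in TAC (0.08 ± 0.01, adjusted p = 0.00109), with 1 and 3 members passing (2 and 4 adjusted over the list alone). Pgam1, phosphoglycerate mutase, had an amplitude of 0.46 ± 0.07 in SHAM and 0.48 ± 0.07 in TAC. The SHAM call of this list held in 21 of its 49 alternatives, and without all arrays of replicate number 2 the adjusted p was 0.272. The mean of 23 angiogenesis and hypoxia genes peaked at ZT22.0 in SHAM (adjusted p = 0.00934) and ZT21.0 in TAC (adjusted p = 0.0058), with 7 and 3 members passing (10 and 6 adjusted over the list alone), among them the growth factor gene Vegfa with amplitudes of 0.27 ± 0.06 and 0.31 ± 0.06. The SHAM call of this list ended without the 4 arrays with thymus or airway transcripts described further on.

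Glucocorticoid targets had a rhythm of their mean in SHAM (amplitude 0.18 ± 0.05, peak ZT11.3, adjusted p = 0.0163), and in TAC the mean had an amplitude of 0.09 ± 0.05 (adjusted p = 0.431). The difference itself did not pass (adjusted p = 0.905). Of 18 members, 9 passed in SHAM and 3 in TAC (10 and 11 adjusted over the list alone). Tsc22d3, the glucocorticoid-induced leucine zipper gene, had amplitudes of 0.39 ± 0.06 and 0.33 ± 0.06. The list of renin, natriuretic and vasoactive genes passed in SHAM (adjusted p = 0.00799) while TAC had an adjusted p of 0.0871, and the difference did not pass (adjusted p = 0.905). In it 5 of 21 members passed in SHAM and 4 in TAC (6 and 5 adjusted over the list alone), and the vasodilator gene Adm peaked at ZT18.1 and ZT17.0. Its SHAM call too ended without those 4 arrays. Unfolded protein response genes had a rhythm of their mean in TAC (0.09 ± 0.02, peak ZT17.8, adjusted p = 0.00109) and a SHAM amplitude of 0.04 ± 0.02 (adjusted p = 0.265), and the difference did not pass (adjusted p = 0.285). In this list 8 of 24 members passed in each surgery (10 in SHAM and 12 in TAC adjusted over the list alone), including Herpud1, a gene of the degradation of endoplasmic reticulum proteins (0.58 ± 0.06 and 0.47 ± 0.06). No member of the oxidative phosphorylation list (38 measured), the tricarboxylic acid cycle list (22), the branched-chain amino acid and ketone list (20) or the calcium handling list (20) passed in either surgery in the limma test. At an unadjusted p under 0.05, 1 and 8 members passed in SHAM and TAC in the first list, 0 and 4 in the next, then 1 and 3, and 2 and 5. Of all 12393 genes, 2331 and 2450 passed at this threshold, so these counts do not single out the lists as rhythmic in TAC. Over the 57 lists, the mean passed for 7 in SHAM and 5 in TAC in the 24-h test and for 8 and 11 in a test for any shape, and these tests of list means were chosen after the values were seen.

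The rhythm itself differed between TAC and SHAM for 6 genes. Arhgap24 had an amplitude of 0.07 ± 0.03 in SHAM and 0.33 ± 0.03 in TAC with a peak at ZT19.4 (adjusted p of the difference = 0.00878). At ZT19 its mean was 0.01 ± 0.06 in SHAM and 0.48 ± 0.07 in TAC (SD, n = 3), each relative to its own surgery's median. Tnfrsf12a, the receptor of the cytokine TWEAK, peaked at ZT3.4 in SHAM and ZT20.4 in TAC (adjusted p = 0.0226). Bhlhe40, a repressor within the clock, peaked at ZT8.58 ± 0.53 in SHAM and ZT4.41 ± 0.46 in TAC (SE, adjusted p = 0.0473). Xirp1 had amplitudes of 0.07 ± 0.07 and 0.56 ± 0.07, and Tlr4, a receptor of innate immunity, 0.11 ± 0.04 and 0.28 ± 0.04. Tmem144 peaked at ZT5.74 in SHAM and ZT19.2 in TAC with amplitudes of 0.10 ± 0.03 in both. The adjusted p was 0.0488 for each of these last 3. At an unadjusted p under 0.05, 777 genes differed where chance alone gives 620. Adjusted over the 1842 genes with a rhythm in either surgery or in common, 18 genes passed. These genes were picked by the same rhythm terms that the difference compares, so the adjusted p over them can be too small. The count was 409 with array weights, 12 after quantile normalization, 3 with an intensity trend in the variance and 2 with atrial and adipocyte marker means as covariates, and leaving out single arrays gave 2 to 8, with 2 or 3 for 25 of the 36 arrays. Leaving out all arrays of replicate number 1, 2 or 3 gave 0.

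Time courses compared without assuming a curve differed for 2 genes. They were Arhgap24 (adjusted p = 0.00267) and Slc2a1, the glucose transporter GLUT1 (adjusted p = 0.0151). Relative to each surgery's median, Slc2a1 was at 0.17 ± 0.07 at ZT11 and -0.13 ± 0.11 at ZT23 in SHAM, and at 0.02 ± 0.10 and 0.39 ± 0.14 in TAC (SD, n = 3). At an unadjusted p under 0.05, 690 genes differed. Without all arrays of replicate number 2, 0 genes differed, and without those of number 1, 20 did. Other settings gave 1 to 20 genes, array weights 1730, and leaving out single arrays 1 to 30.

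Clock genes peaked earlier in TAC than in SHAM. Over the 17 clock list members with a rhythm common to both surgeries, the median TAC minus SHAM peak time was -0.98 h, and 15 of 17 were earlier in TAC (permutation p = 0.0396, two-sided, 100000 relabellings). The shift was -1.48 ± 0.44 h for Dbp, -1.71 ± 0.52 h for Nr1d2, -1.31 ± 0.55 h for Arntl and -4.16 ± 0.71 h for Bhlhe40 (SE). Cry2 had a shift of 1.65 ± 1.01 h. This test was chosen after the values were seen, and p lay above 0.05 without any of 12 single arrays, reaching 0.0737 without SHAM ZT03 replicate 1. The 232 other genes rhythmic in both surgeries had a median shift of -0.65 h. The planned comparison of amplitudes did not pass. The median TAC amplitude was 0.841 of that in SHAM, with 13 of 17 members lower in TAC (permutation p = 0.0678, two-sided, 100000 relabellings). The ratio was 0.589 for Usp2 and 0.662 for Per2, and 1.26 for Nfil3. The clock amplitude comparison passed after quantile normalization (permutation p = 0.0422) and without TAC ZT23 replicate 3 (permutation p = 0.00105), SHAM ZT11 replicate 3 (0.0261) or SHAM ZT11 replicate 1 (0.039) and without all arrays of replicate number 3 (0.00195). It also passed, narrowly, with the replicate number as a block, as given further on. Its direction turned with the mean of the matrix genes as a covariate.

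**Figure D3:**
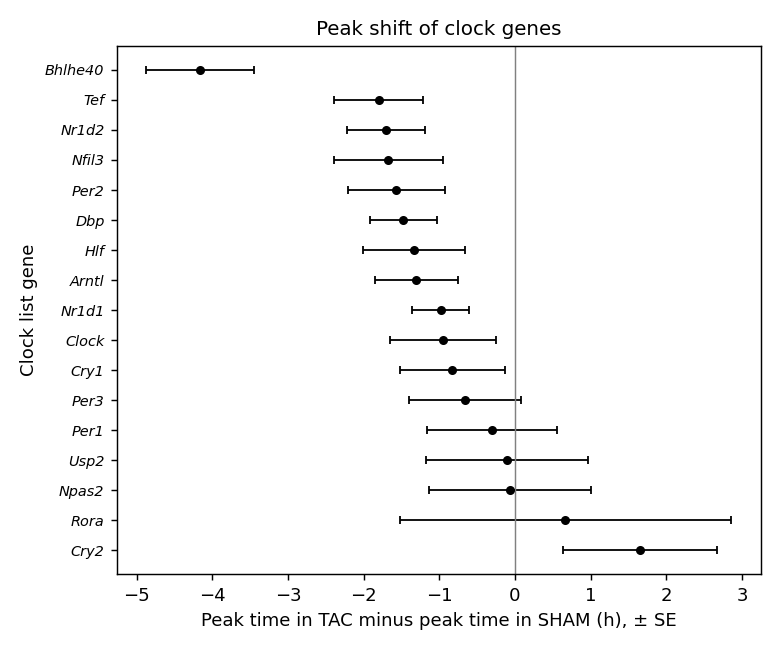
Peak time in TAC minus peak time in SHAM, in h, for the 17 clock list genes with a common rhythm. Points are fitted differences with their SE, and 15 of 17 lie below 0.

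Mice of the same group differed more from each other after TAC than after SHAM. The SD within a group was higher in TAC for 8911 of 12393 genes (71.9%), and the median ratio of SDs was 1.23. Of 100 assignments of surgery within time, the real one included, 2 gave a median as far from 1, and for the log2 ratio the other reached 0.30 in size against 0.29. Of the 57 lists, the log2 ratio was highest in those of fibrosis. Over 31 fibrillar collagen and matrix genes the median log2 ratio of the TAC to the SHAM SD was 1.63, and all 31 were more variable in TAC (adjusted p = 5.18e-04). The 12 activated fibroblast markers had a log2 ratio of 1.98 with 11 more variable in TAC, and the 20 genes of the hypertrophy and fetal programme a log2 ratio of 0.99 with 19 more variable (adjusted p = 5.18e-04 for each). The cardiomyocyte markers had a log2 ratio of 0.30 (adjusted p = 0.0527), and the atrial markers 0.14 (adjusted p = 0.539). Of the 57 lists, 35 passed in this permutation test, 1 of them, the thymocyte list, being less variable in TAC, where the SHAM spread came from SHAM ZT11 replicate 3 (mean 2.07, against at most 0.06 on the other SHAM arrays). The raw p of 1.0e-04 behind the first 3 lists is the smallest that 10000 relabellings can give. These tests were chosen after the values were seen.

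Myh7, the beta myosin heavy chain that rises in loaded mouse hearts, and Postn, which encodes the matrix protein periostin, showed this spread plainly and are named after their values were seen. The SD of Myh7 within a group was 0.12 in SHAM and 0.77 in TAC. In TAC, Myh7 was at 1.38 ± 0.36 at ZT23 and -0.86 ± 0.90 at ZT19 (SD, n = 3), and a change over the 6 times of any shape passed for Myh7 (adjusted p = 0.00261) and Postn (adjusted p = 0.0117). In SHAM it did not (adjusted p = 0.981 and 0.999). This test used 1 estimate of the spread per gene over both surgeries. For these genes it was lenient in TAC, where mice varied more, and strict in SHAM. The change was not tested with the spread of the TAC arrays alone. In TAC, atrial markers moved with Myh7 in the opposite direction at these times, their mean being -0.61 ± 0.24 at TAC ZT23 and 0.23 ± 0.26 at TAC ZT19, where the matrix list was at 0.44 ± 0.13 and -0.19 ± 0.22 (SD, n = 3). The difference in time course between the surgeries did not pass for Myh7 (adjusted p = 0.336) or Postn (adjusted p = 0.62), nor for any gene of the hypertrophy, matrix and activated fibroblast lists over all genes in limma. Adjusted over the list alone, it passed for 12 of 20 hypertrophy genes, 9 of 31 matrix genes and 7 of 12 activated fibroblast markers. For the means of these lists it did not pass (adjusted p = 0.38, 0.237 and 0.135 over the 57 lists). Over the 18 TAC mice, Myh7 followed the mean of the matrix list with Pearson's r = 0.917 and Spearman's rho = 0.932 (permutation adjusted p = 2.0e-05 and 3.0e-05 over 6 relations, raw p of 1.0e-05 being the smallest possible), and r was 0.928 without the 2 arrays farthest from the median. Over the 18 SHAM mice r was -0.35 (adjusted p = 0.219) and rho -0.53 (adjusted p = 0.0352), with r at -0.26 without the 2 farthest arrays.

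**Figure D4:**
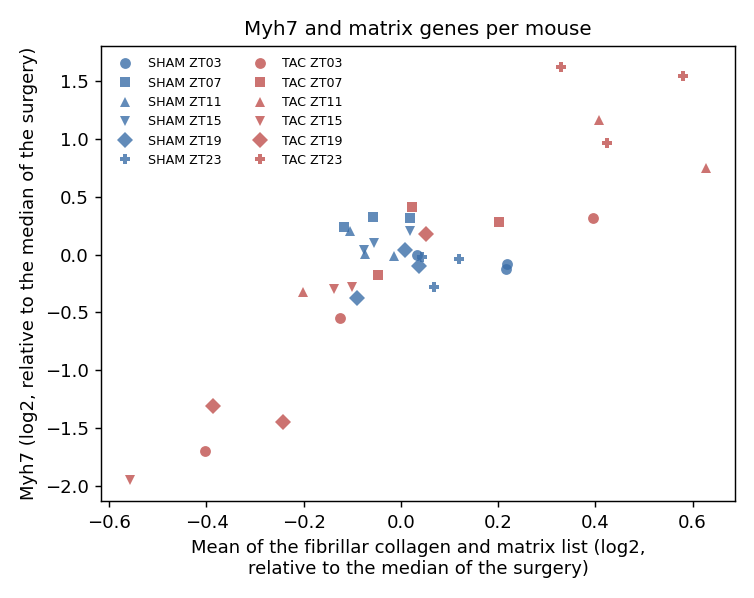
Myh7 against the mean of the fibrillar collagen and matrix list for each of the 36 mice, both log2 and relative to the median of the surgery, with colours for the surgeries and symbols for the times of day. The TAC mice spread from -1.95 to 1.62 in Myh7, and Pearson's r over them is 0.917.

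Transcripts of other tissues stood out on single arrays, and Rag1, Adipoq, Myl7 and Nppa are named after their values were seen. SHAM ZT11 replicate 3 had a mean of 2.07 over 9 thymocyte markers, and its Rag1, a recombinase gene of lymphocyte precursors, was at 5.68. The mean of 5 airway epithelium genes, a list written after the values were seen, was 3.59 on TAC ZT23 replicate 1, 2.88 on TAC ZT03 replicate 3 and 2.3 on SHAM ZT23 replicate 3. Without these 4 arrays, 691 genes were rhythmic in SHAM and 638 in TAC, 4 differed in rhythm and 17 in time course. The genes were not all the same: 599 of the 692 SHAM calls, 455 of the 539 TAC calls and 3 of the 6 differences in rhythm were kept. Adiponectin (Adipoq) ranged from -1.95 to 3.31 over the arrays. Atrial markers changed over the day in any shape in SHAM (adjusted p = 0.0495) and TAC (adjusted p = 0.00382) as a list mean, and the difference in time course did not pass (adjusted p = 0.135). For single members, that difference passed for 0 of 11 over all genes and for 6 adjusted over the list alone. Myl7, the atrial myosin light chain, was at -2.27 ± 0.84 at TAC ZT23 and 0.60 ± 0.49 at TAC ZT19 (SD, n = 3). Nppa, which encodes atrial natriuretic peptide, had an amplitude of 0.42 ± 0.11 (SE, n = 18) in SHAM with a peak at ZT18.9 (adjusted p = 0.0406, a call held in 34 of 50 alternatives), while Myl7 in SHAM had an amplitude of 0.49 ± 0.24 and a peak at ZT19.1 (adjusted p = 0.411).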

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

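The tests of the clock peak shift, of the cold-inducible list mean, of the sampling offset, of the 4 arrays with transcripts of other tissues, of connective tissue and of the atrial covariate with a slope per surgery were chosen after the values had been seen. Counts over rearranged labels, the atrial covariate with a common slope and the correlation among mice of the same time were set down before their results.

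The difference between TAC and SHAM itself passed for the rhythm of Arhgap24 (adjusted p = 0.00878), Tnfrsf12a (0.0226), Bhlhe40 (0.0473), and Tlr4, Tmem144 and Xirp1 (0.0488 each), all by limma. The call held for Arhgap24 in 47 of 50 alternatives, for Tnfrsf12a in 45, for Bhlhe40 in 21, for Xirp1 in 14, for Tmem144 in 13 and for Tlr4 in 11. Leaving out single arrays ended no call of Arhgap24, and leaving out TAC ZT19 replicate 3 ended that of Tnfrsf12a. The count fell to 2 or 3 without any single array except SHAM ZT07 replicates 1 and 2, SHAM ZT11 replicate 3, SHAM ZT19 replicate 3, TAC ZT03 replicate 3, TAC ZT07 replicate 3, TAC ZT15 replicates 1 and 2, TAC ZT19 replicate 2 and TAC ZT23 replicates 2 and 3. Of 100 splits of the arrays by surgery within time, the real one included, 1 gave as many genes. The real split gave 6 and the others at most 2, a share under the bound set beforehand. Yet the count fell to 2, the highest of the other splits, without some single arrays. It fell to 0 without all arrays of any 1 replicate number, so the share alone does not exclude chance for the count. The time course differed for Arhgap24 (adjusted p = 0.00267) and Slc2a1 (0.0151). Here 3 of 100 splits, the real one included, gave at least 2 genes, under the bound set beforehand. The other splits among the 3 gave 37 and 42 genes, far above the real 2, so that share does not exclude chance for this count. Such splits point to a structure among the arrays beyond surgery and time. The count was 1 without SHAM ZT23 replicate 1 or 2, each of which ended the call of Slc2a1, as did TAC ZT23 replicate 1. It was 30 without TAC ZT11 replicate 1, 27 without TAC ZT23 replicate 3, 23 without TAC ZT03 replicate 3, 16 without TAC ZT15 replicate 1, 11 without TAC ZT19 replicate 1 and 7 without TAC ZT11 replicate 2. It was 5 without TAC ZT07 replicate 1, TAC ZT15 replicate 3 or TAC ZT23 replicate 2, and 4 without TAC ZT15 replicate 2 or TAC ZT23 replicate 1.

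The rhythm of the mean of the cold-inducible RNA-binding list differed between the surgeries (adjusted p = 0.0231), with amplitudes of 0.20 ± 0.03 in SHAM and 0.05 ± 0.03 in TAC (SE, n = 18). Only 4 members were measured, under the planned minimum of 5. Cirbp had amplitudes of 0.55 ± 0.08 and 0.15 ± 0.08, while Hspa8, a chaperone gene that peaked at ZT19.1, is also in the heat shock list. No single member passed the test of the difference over all genes, and 2 did adjusted over the list alone. The call held in 37 of 49 alternatives and ended without SHAM ZT11 replicate 3, SHAM ZT23 replicate 3, TAC ZT11 replicate 2 or 3, or TAC ZT23 replicate 2, and the adjusted p reached 0.984 without replicate number 2.

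Clock genes peaked earlier in TAC (median -0.98 h, permutation p = 0.0396), with p between 0.0508 and 0.0737 without SHAM ZT03 replicate 1 or 3, SHAM ZT07 replicate 2 or 3, any SHAM ZT15 array, SHAM ZT23 replicate 1, TAC ZT07 replicate 2 or 3, TAC ZT11 replicate 1 or TAC ZT19 replicate 1. Transcripts of thymus or airway on 4 arrays do not account for it, since the shift was -1.28 h without them. An offset in the sampling time of the TAC mice would move all rhythmic genes, and the 232 other genes rhythmic in both surgeries had a median shift of -0.65 h, with 155 earlier in TAC, so such an offset may contribute. An earlier clock in the loaded heart, which would move its output genes too, stays open and was not told apart from it by any test here.

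Myh7 and the mean of the matrix genes passed a test for a change of any shape between times in TAC (adjusted p = 0.00261 and 0.00928). This test used 1 estimate of the spread over both surgeries, which is lenient for the more variable TAC mice, so the change itself is not settled. More connective tissue in some samples would not raise a cardiomyocyte gene, yet Myh7 followed the matrix list over the 18 TAC mice (Pearson's r = 0.917), which argues against it for Myh7, a gene named after its values were seen, and leaves it open for the matrix genes themselves. The response to constriction may have varied from mouse to mouse: among mice of the same time, the deviations of Myh7 and the matrix list from their time means had r = 0.85 and rho = 0.777 (adjusted p = 2.0e-05 and 4.8e-04), with r = 0.81 without the 2 farthest arrays, against r = 0.173 and rho = 0.096 in SHAM (adjusted p = 0.492 and 0.706; r = 0.311 without the 2 farthest). Atrial markers moved with the pattern, with a mean of -0.61 ± 0.24 at TAC ZT23 (SD, n = 3), where Myh7 was at 1.38 ± 0.36, so a varying share of atrial tissue stays open as well. With 3 mice at each time, such a spread can give groups that differ without a daily cause, and a daily change of these genes stays open.

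Rhythm counts were set against 100 arrangements of the time labels within a surgery, the real one included. In SHAM 1 gave as many genes, with 692 in the real order and at most 28 in the others, so chance can be excluded. In TAC also 1 did, with 539 in the real order, a share under the bound set beforehand. Yet other arrangements gave 513, 316, 241, 156, 121 and 103 genes, the highest of them close to the real count. The share therefore does not exclude chance for the TAC count, and these arrangements point to a structure among the TAC arrays.

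Nppa followed a 24-h rhythm in SHAM, as atrial markers varied. Over the 18 SHAM mice Nppa followed the mean of the 10 other atrial markers (r = 0.971, rho = 0.971, adjusted p = 2.0e-05 and 3.0e-05, r = 0.973 without the 2 farthest arrays), and over the 18 TAC mice it did not (r = -0.329, rho = -0.304, adjusted p = 0.219 and 0.262, r = -0.0967 without the 2 farthest). With the markers as a covariate of common slope, 0.827 of the amplitude remained (0.35 ± 0.12), just past the bound of 0.8 set beforehand against a varying share of atrial tissue, by less than its SE. That slope was shared by surgeries whose relations differ, so a slope per surgery was then tried, which left 0.202 of the amplitude (0.08 ± 0.09, adjusted p = 0.817). A varying share of atrial tissue in the SHAM samples is a candidate explanation, found on these data, and a rhythm common to atrial genes and Nppa stays open.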

How the results depend on the processing

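The alternatives using probe set choice, less variable genes, covariates and the omission of 4 arrays, and the tests of list means, clock peak shift and spread were chosen after the data had been seen. The dimness filters, the brightest probe set rule, the pseudocount and every alternative of the TAC against SHAM level comparisons were not run, because the centred values hold no levels. The SHAM rhythm count of 692 was 1393 after quantile normalization, 3126 with array weights, 418 for any shape, 1166 from the SHAM arrays alone and 117 at a fold of at least 1.5. The TAC count of 539 was 2298 with array weights, 652 for any shape, 142 from the TAC arrays alone and 77 at that fold. TAC had more rhythmic genes than SHAM for any shape, with the matrix list as a covariate (738 against 540) and without SHAM ZT03 replicate 3 (617 against 601). The same held at an unadjusted p under 0.05 in the limma test (2450 against 2331). The array weights ran from 0.247 to 4.98, and the cause of the rise was not tested. The 6 genes with a difference of rhythm became 12 after quantile normalization, 409 with array weights, 3 with the trend and 2 with marker covariates. They became 18 adjusted over rhythmic genes, a set picked by the same rhythm terms, which can make the adjusted p too small. The 2 genes with a difference in time course became 12 after quantile normalization, 1730 with array weights, 1 with the probe set of largest SD, with marker covariates or with each probe set by itself, 20 without the less variable genes and 17 without the 4 arrays with thymus or airway transcripts. The log2 clock amplitude ratio of -0.25 was -0.38 after quantile normalization (permutation p = 0.0422) and 0.025 with the matrix list as a covariate (permutation p = 0.847). For each of these the cause was not tested, beyond the smaller set of genes or arrays where the setting has one.

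Whether same-numbered arrays pair was not clear: 66 of 198 such pairs had residual correlations over 0.1 (mean 0.038, against -0.019 for different numbers). Of 36 arrays, 23 correlated best with their own number. That is more often than chance among the numbers would give, a hint from the data and not the design. With the replicate block, 2 genes differed in rhythm, and the clock amplitude ratio of -0.25 had a permutation p of 0.0477. It moved no other count by over 1.5 times (726 in SHAM, 565 in TAC, 3 for the time course), kept the call of the clock peak shift and, of the calls of list means, ended only that of glycolysis in SHAM.

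Leaving out arrays or replicate numbers gave 119 to 777 rhythmic genes in SHAM, 116 to 618 in TAC, 0 to 8 genes with a difference of rhythm and 0 to 30 with a difference in time course. The log2 clock amplitude ratio ranged from -0.48 to -0.20 and the clock peak shift from -1.57 to -0.90 h (p up to 0.144). The log2 SD ratio ranged from 1.28 to 1.76 for matrix genes, 1.12 to 2.13 for activated fibroblast markers and 0.45 to 1.40 for the hypertrophy list, and each passed in every alternative run, the matrix ratio being 1.08 after quantile normalization. With 25 of 36 single arrays left out, 2 or 3 genes differed in rhythm. The number of arrays, 3 per group, limits all of these.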

Other observations

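The tests of list means were chosen after the values were seen. Single members of other lists were rhythmic, while the list means of the endothelial, basement membrane and matrix protease genes did not pass the 24-h test in either surgery (adjusted p from 0.11 to 0.985). In a test for any shape, the matrix protease mean passed in TAC (adjusted p = 0.0483) and had an adjusted p of 0.978 in SHAM, and the difference in time course did not pass (adjusted p = 0.237). Of 18 endothelial markers measured, 7 were rhythmic in SHAM and 3 in TAC (9 and 11 adjusted over the list alone). Cldn5, a tight junction gene, peaked at ZT23.1 with an amplitude of 0.38 ± 0.06 in SHAM and at ZT22.0 with 0.40 ± 0.06 in TAC (SE, n = 18). The water channel gene Aqp1 had amplitudes of 0.33 ± 0.04 and 0.15 ± 0.04, the second not passing (adjusted p = 0.0972), and its difference did not pass (adjusted p = 0.789). Of 18 basement membrane genes, the collagens Col4a1 and Col4a2 were rhythmic in each surgery (6 in SHAM and 3 in TAC adjusted over the list alone), Col4a1 with amplitudes of 0.37 ± 0.07 and 0.33 ± 0.07. Of 19 matrix protease and inhibitor genes, 5 were rhythmic in SHAM and 3 in TAC (6 and 4 adjusted over the list alone), and Timp3 peaked at ZT12.8 and ZT12.4. The TAC call of Timp3 held in 29 of 50 alternatives.

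Of 19 proteostasis and atrophy genes, 5 were rhythmic in SHAM and 4 in TAC (8 and 4 adjusted over the list alone). The ubiquitin ligase gene Fbxo32 peaked at ZT7.04 in SHAM and ZT6.16 in TAC with amplitudes of 0.45 ± 0.07 and 0.43 ± 0.07. Fasting-response genes of the PPAR-alpha list changed over the day in any shape as a list mean in SHAM (adjusted p = 4.59e-04) while TAC had an adjusted p of 0.251, and the difference in time course did not pass (adjusted p = 0.0675), with 4 and 1 of 18 members passing the 24-h test (5 and 1 adjusted over the list alone). For single members, the difference in time course passed for 0 over all genes and for 7 adjusted over the list alone. Ucp3, a mitochondrial uncoupling protein gene, had amplitudes of 0.56 ± 0.09 and 0.19 ± 0.09, and the difference of its rhythm did not pass (adjusted p = 0.748). Cell cycle genes had 0 of 26 members passing in either surgery by limma, and 1 and 2 members in SHAM and TAC at an unadjusted p under 0.05. Of all 12393 genes, 2331 and 2450 passed at that threshold.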
